A study of Mus musculus with 41 samples.

How the data were processed

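RNA of 41 mammary samples from female FVB mice was measured on 2-colour Agilent 4x44K mouse arrays. The samples were 11 normal glands, of which 6 were pools of several mice, and 30 tumours: 8 Met, 14 MetTrp53 and 8 Trp53. Per the labels, tissue was snap-frozen, RNA was extracted with a Qiagen Allprep kit and amplified in 1 round with Amino Allyl MessageAmp II. Each sample was labelled with Cy3 and hybridised with Stratagene universal mouse reference RNA in Cy5, in 1 orientation. Groups, pathology, parity, pooling and animal were taken from the labels.

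Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1 and hold mean spot intensity and median local background intensity for each channel. They also hold processed intensities that were background-subtracted, detrended and dye-normalized (linear and lowess), and other columns of 0 and 1 that mark spots as saturated, outlying or well above background, per the file headers. The deposited value table holds log2 ratios of sample over reference that the authors normalized within each array. The authors name limma 3.12.1 and RMA without settings, so its background and normalization steps stay unknown. Checked against the scanner files, the deposited values ran in the direction of sample over reference on the log2 scale, with array medians from -0.13 to 0.060. Their correlation with the values used here was 0.799 to 0.983, with slopes of 1.16 to 1.5.

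Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 (statmod 1.5.0, the package data.table at 1.17.8, jsonlite 2.0.0). Outlying spots, 0.265% to 0.742% of an array, were left out, and spots of 1 probe were averaged. The 41174 probes were matched to current gene names by accession (22951), symbol (6659) or synonym (3109), and 8455 kept the name in the file. Probe positions are those of build mm7 in the files. Of the 27670 names, 8914 had more than 1 probe, and the probe with the highest mean brightness over the 41 arrays stood for the gene. In tumours against normal glands, 3833 called genes had another probe, which passed with the same sign in 2785 and with the opposite sign in 147. Genes were tested where the probe was well above background in Cy3 on at least 8 arrays, which left 20678.

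The 7 comparisons of groups used 1 limma fit of all 41 arrays with 4 groups (lmFit and eBayes). Spindloid against other tumours used 26 tumours with genotype as a covariate, the interaction 18 tumours, and parity the 11 normal glands. Adjusted p values are Benjamini and Hochberg's, and genes passed under 0.05. Pathology was compared with Fisher's exact test, 2-sided, adjusted over 3 pairs. Titles give 6 animals with 2 samples each. The residuals correlated with r of 0.11 to 0.15 in 5 of these pairs and -0.14 in the other. The main fit took them as unpaired, and the animal as a random block (consensus correlation 0.106) was an alternative.

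Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists within a comparison, beside camera with an estimated correlation and fry. Beside the genes of the model, the lists cover adipocyte, B cell and plasma cell, basal and myoepithelial, EMT transcription factors, endothelial, epithelial adhesion and identity, ERK pathway output, fibroblast and matrix, growth factor receptors, hypoxia and glycolysis, interferon response, luminal, macrophage, mesenchymal genes, Met neighbours on chromosome 6, Met signalling, milk, nerve and Schwann cell, neutrophil, p53 targets, pericyte and smooth muscle, proliferation, red blood cell, skeletal muscle, squamous differentiation, stem cell and progenitor, T cell, tight junction and claudin and Wnt pathway targets. Each was written from general knowledge of the genes. Genes named in the text were those of a fixed rule. It takes Met, Trp53, Hgf, Cldn1, Cldn3, Cldn4, Cldn7, Cdh1, Vim and Twist1 in every comparison, the 6 highest and 6 lowest log2 fold changes that passed, and up to 4 members of each list that passed and 2 that did not. The text names part of these. Eef1a1 and Tpt1 were chosen after their values were seen. The groups, comparisons, lists, naming rule, tests and most alternatives were fixed before the data were examined.

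The alternatives were Feature Extraction's processed intensities, median centring, scaling between arrays, an offset of 16, the mean of all probes, no filter, a filter at 21 arrays, the deposited values, array weights, slide or animal as a random block, scan date as a block or within 1 date, parity (not given as its own level), pathology or pooling as a covariate, fits of the compared arrays alone, fits without pooled glands, 1 tumour per animal, other uses of the Intermediate tumours, and leaving out each array. Scan period (runs of scan dates with gaps between them) and, for the interaction, the animal were added after the data were seen. As a covariate, pathology was spindloid, Intermediate or other. Labels were also regrouped 100 times at random, the real grouping included. Simulated data had 100 genes changed 2-fold, 100 4-fold and 1 list shifted. Recovery was 61% to 75% and 91% to 96% in the first 8 comparisons. It was 6% and 48% for the interaction and 28% and 77% for parity. The 5 to 13 false calls need not hold for real arrays, where regrouping called up to 7180. Figures used matplotlib 3.10.9 under Python 3.11.15.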

Results

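Gene expression was measured in 41 mammary samples from female FVB mice: 11 normal glands and 30 mammary tumours. The tumours comprised 8 from mice with the MMTV-Met transgene, which places the Met receptor under a promoter active in mammary epithelium (Met tumours). Another 14 came from mice that also carried 1 conditional allele of the tumour suppressor Trp53 and Cre recombinase (MetTrp53 tumours), and 8 from mice with the Trp53 allele and Cre and no transgene (Trp53 tumours). The normal glands came from wild-type mice and mice of the 3 genotypes and were taken as 1 group. Each sample (Cy3) was hybridised with the same universal mouse reference RNA (Cy5), so every value was a log2 ratio of sample over reference. Between 58.0% and 76.2% of the spots of an array lay well above background in the sample channel, and its median intensity ran from 163 to 471. The number of arrays limits the precision. Correlations of log ratios between arrays had a median of 0.806 within a group and 0.579 between groups, and the lowest was 0.348.

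The arrays were scanned in 3 periods. Period 1 held 5 normal glands, 8 Met and 10 MetTrp53 tumours. Period 2 held 6 normal glands, 4 MetTrp53 and 5 Trp53 tumours, and period 3 held 3 Trp53 tumours. All 6 normal glands of period 2 were pools of several mice and all 5 of period 1 were single mice, so pooling and period cannot be told apart among them. Between periods 2 and 1, 7180 genes differed among normal glands and 2682 among MetTrp53 tumours (limma, adjusted p under 0.05), and the shifts of the 2 groups correlated across 20677 genes with r = 0.62, where genes are not independent replicates. The housekeeping genes Eef1a1, an elongation factor, and Tpt1 were higher in period 2 by 2.48 ± 0.30 (log2, SE) and 2.24 ± 0.20 in normal glands and by 2.73 ± 0.21 and 2.44 ± 0.24 in MetTrp53 tumours. Met and Trp53 tumours shared no period.

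**Figure D1:**
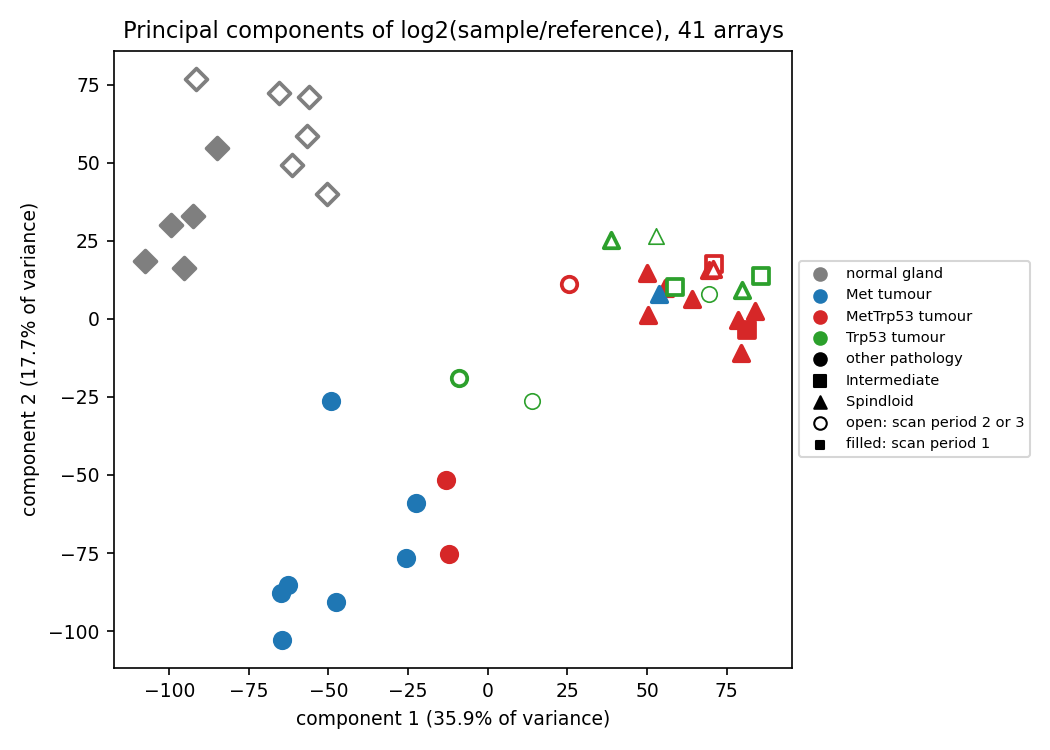
Principal components of the log2 ratios of the 41 arrays, component 1 (35.9% of the variance) against component 2 (17.7%), each point an array coloured by group, shaped by pathology and filled for scan period 1. Normal glands, the Met tumours of other pathology and the spindloid tumours lie in 3 separate areas, and the 1 spindloid Met tumour lies among the spindloid MetTrp53 and Trp53 tumours.

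Met, the receptor of hepatocyte growth factor, was high in MetTrp53 and Trp53 tumours and did not differ between Met tumours and normal glands at the probe used here. At that probe (chromosome 6, 17514221 to 17514280, build mm7), the log2 ratio was 0.97 ± 1.13 (SD, n = 11) in normal glands, 1.03 ± 2.21 (n = 8) in Met, 4.33 ± 0.23 (n = 14) in MetTrp53 and 3.37 ± 1.5 (n = 8) in Trp53 tumours. The Met tumours were not alike, at 4.53, 4.33 and 1.46 in tumours 4, 5 and 3 and -0.90 to -0.046 in the other 5. The 3 probes of Met differed in Met tumours. Against normal glands, the probe at 17493755 rose by 2.83 ± 0.48 (adjusted p = 1.22e-05), while those at 17513642 and 17514221 had differences of 0.51 ± 0.55 (adjusted p = 0.484) and 0.069 ± 0.59 (adjusted p = 0.939). In MetTrp53 tumours the 3 probes rose by 3.74 ± 0.41 (adjusted p = 1.35e-09), 3.32 ± 0.47 (adjusted p = 2.95e-07) and 3.36 ± 0.51 (adjusted p = 8.33e-07), and in Trp53 tumours, which carry no transgene, by 1.99 ± 0.48 (adjusted p = 8.95e-04), 2.43 ± 0.55 (adjusted p = 4.55e-04) and 2.40 ± 0.59 (adjusted p = 0.00113). The 2 probes of Trp53 also differed. The probe at chromosome 11, 69671206 fell in MetTrp53 tumours by 1.43 ± 0.26 (adjusted p = 1.70e-05) and in Trp53 tumours by 0.86 ± 0.30 (adjusted p = 0.019) against normal glands, and the probe used, at 69662031, had differences of -0.13 ± 0.14 (adjusted p = 0.458) and 0.034 ± 0.16 (adjusted p = 0.884).

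Tumours of the 3 genotypes, weighted equally, were first compared with normal glands. In this mean over the genotypes, cell division genes rose, and genes of fat, muscle and differentiated gland fell, though in Met tumours the milk, luminal and epithelial lists were not called (below). All list calls here and below are those of camera at its preset correlation; with an estimated correlation it called no list in any of the 10 comparisons (lowest adjusted p = 0.069). Where no count of a list's genes adjusted over the list alone is given, it was the same as that over all genes tested. Among proliferation genes, 28 of 28 measured rose and 0 fell. The median log2 fold change was 1.97 (camera adjusted p = 5.08e-27). Among them were Ube2c (2.69 ± 0.19, adjusted p = 2.44e-14) and Top2a (2.56 ± 0.20, adjusted p = 1.98e-13), which act in mitosis and chromosome segregation (log2 fold change ± SE here and below). Among genes of ERK pathway output, 12 of 17 measured rose and 0 fell. Their median log2 fold change was 1.27 (camera adjusted p = 1.42e-05). These included the transcription factors Etv4 (3.15 ± 0.26, adjusted p = 1.16e-12) and Fosl1 (2.87 ± 0.52, adjusted p = 1.53e-05) and cyclin D1 Ccnd1 (2.23 ± 0.24, adjusted p = 5.26e-10). Among Met and the genes next to it on chromosome 6, 8 of 14 measured rose and 0 fell. As a list they had a median of 0.93 (camera adjusted p = 0.0080). These included Tes (2.06 ± 0.55, adjusted p = 0.00203) besides Met (1.94 ± 0.45, adjusted p = 4.81e-04).

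Fat and muscle genes fell most. Among adipocyte genes, 16 of 16 measured fell and 0 rose. Across the list the median was -3.04 (camera adjusted p = 2.17e-09). They included Lpl (-4.66 ± 0.45, adjusted p = 4.22e-11) and the adipogenic receptor Pparg (-4.21 ± 0.24, adjusted p = 9.23e-17). Among skeletal muscle genes, 14 of 14 measured fell and 0 rose. The list had a median log2 fold change of -3.12 (camera adjusted p = 7.10e-07). Fibre proteins and muscle enzymes held 5 of the 6 largest decreases, such as Actn3 (-6.33 ± 0.54, adjusted p = 2.65e-12). Of gland genes, medians were -1.55 for basal and myoepithelial (14 of 15 fell, adjusted p = 2.16e-05), -1.37 for luminal (12 of 15 fell, adjusted p = 0.00418) and -1.91 for milk (6 of 11 fell, adjusted p = 0.0111), with the oestrogen receptor Esr1 (-2.27 ± 0.24, adjusted p = 3.87e-10) among the luminal genes. The largest increases included the prolactin relative Prl2c3 (5.05 ± 0.93, adjusted p = 2.07e-05) and the tumour suppressor locus Cdkn2a (3.91 ± 0.31, adjusted p = 3.03e-13).

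Epithelial adhesion genes fell in the mean over the genotypes, though in Met tumours their median was 0.29. Among genes of epithelial adhesion and identity, 14 of 24 measured fell and 0 rose (16 and 0 adjusted over the list alone). Together they had a median of -1.22 (camera adjusted p = 0.00649). These included Krt19 (-3.58 ± 0.84, adjusted p = 5.51e-04) and Epcam (-2.52 ± 0.81, adjusted p = 0.00927). Of the claudins, which seal tight junctions, Cldn3 (-1.25 ± 0.30, adjusted p = 6.95e-04), Cldn4 (-1.30 ± 0.48, adjusted p = 0.023) and Cldn7 (-2.68 ± 0.76, adjusted p = 0.00378) fell, and Cldn1 (0.77 ± 0.42, adjusted p = 0.125) did not pass. Hgf, the ligand of Met, rose by 1.19 ± 0.39 (adjusted p = 0.012), a call that ended with scan date or period as a block, at 0.83 (adjusted p = 0.0735) and 0.85 (adjusted p = 0.0554). Of its 3 other probes 1 rose, by 1.03 ± 0.31 (adjusted p = 0.00609), and 2 did not pass, at -0.25 ± 0.17 (adjusted p = 0.237) and 0.0098 ± 0.13 (adjusted p = 0.956). Cdh1 (-0.12 ± 0.46, adjusted p = 0.852), Vim (0.30 ± 0.56, adjusted p = 0.683), Twist1 (0.23 ± 0.46, adjusted p = 0.704) and Trp53 (-0.012 ± 0.12, adjusted p = 0.943) did not pass, and the other probe of Trp53 fell by 0.76 ± 0.23 (adjusted p = 0.00647). Markers of other cell types moved too. Medians were -1.21 for B cell and plasma cell (1 of 12 rose and 9 fell, 2 and 9 adjusted over the list alone, adjusted p = 8.72e-04), -1.0 for T cell (11 of 14 fell, adjusted p = 6.65e-04), -1.35 for pericyte and smooth muscle (7 of 10 fell, adjusted p = 0.00253) and -0.41 for endothelial (7 of 13 fell, adjusted p = 0.0278).

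The other 16 of the 29 lists were not called by camera. Their median log2 fold changes were -1.09 for tight junction and claudin (0 of 14 rose and 6 fell, adjusted p = 0.16), -0.27 for EMT transcription factors (1 of 9 rose and 2 fell, 1 and 1 adjusted over the list alone, adjusted p = 0.952), 0.23 for mesenchymal genes (6 of 18 rose and 0 fell, adjusted p = 0.139), 0.16 for Met signalling (8 of 17 rose and 1 fell, adjusted p = 0.16), -0.24 for p53 targets (5 of 28 rose and 11 fell, adjusted p = 0.281). They were 0.20 for interferon response (2 of 17 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.539), 0.61 for hypoxia and glycolysis (7 of 16 rose and 4 fell, 7 and 5 adjusted over the list alone, adjusted p = 0.488), -0.21 for Wnt pathway targets (5 of 16 rose and 4 fell, adjusted p = 0.758), -0.39 for stem cell and progenitor (2 of 14 rose and 6 fell, adjusted p = 0.488), -0.52 for growth factor receptors (3 of 18 rose and 7 fell, adjusted p = 0.758). The last 6 were -0.034 for squamous differentiation (2 of 12 rose and 1 fell, adjusted p = 0.899), 0.12 for fibroblast and matrix (2 of 16 rose and 3 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.99), -0.026 for macrophage (2 of 15 rose and 5 fell, adjusted p = 0.863), -0.21 for neutrophil (3 of 10 rose and 1 fell, adjusted p = 0.688), -0.75 for nerve and Schwann cell (1 of 9 rose and 6 fell, adjusted p = 0.16), -0.49 for red blood cell (0 of 6 rose and 2 fell, 0 and 4 adjusted over the list alone, adjusted p = 0.19). With an estimated correlation their adjusted p values ran from 0.337 to 0.997. The median and the mean of the list differed in sign for Wnt pathway targets (mean 0.013), fibroblast and matrix (mean -0.16), macrophage (mean 0.022), neutrophil (mean 0.20).

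In all, 9951 of 20678 genes passed an adjusted p of 0.05, 4505 higher and 5446 lower in tumours. The count was 10109 with slide as a random block, 10127 with scan date and 10242 with scan period as a block. No gene list that camera called turned its direction, with medians between -3.14 for skeletal muscle and 1.94 for proliferation with scan period as a block. The share of genes that were higher depended on scaling: median centring gave 6521 higher and 4920 lower, and the deposited values gave 6401 and 5076, with the median gene moved by 0.104.

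Met tumours were compared with normal glands, of which 7 of 11 also carried the transgene, so the comparison sets tumour against gland more than transgene against none. Claudin 1 rose, and mesenchymal transcription factors fell. Claudin 1 (Cldn1) rose by 2.77 ± 0.55 (adjusted p = 1.18e-04), a fold of 6.8, while Cldn3 (-0.29 ± 0.39, adjusted p = 0.584), Cldn4 (0.73 ± 0.62, adjusted p = 0.366) and Cldn7 (0.079 ± 1.0, adjusted p = 0.959) and the adhesion protein E-cadherin, Cdh1 (1.43 ± 0.60, adjusted p = 0.0564), did not pass. The claudin list (0.69, camera adjusted p = 0.185) and the epithelial adhesion list (0.29, camera adjusted p = 0.352) were not called. Among transcription factors of epithelial to mesenchymal transition (EMT), 7 of 9 measured fell and 0 rose. Over all members the median was -1.98 (camera adjusted p = 0.00657). They included Zeb2 (-2.01 ± 0.38, adjusted p = 5.16e-05) and Twist1 (-1.98 ± 0.60, adjusted p = 0.00802). Vimentin, a filament of mesenchymal cells, fell by 2.26 ± 0.73 (adjusted p = 0.0136). Markers of other cells fell as well, so the tissue's mix of cells may account for these changes. Medians of the other called lists were -0.95 for fibroblast and matrix (6 of 16 fell, adjusted p = 0.0135), -2.52 for adipocyte (11 of 16 fell, adjusted p = 4.63e-07), -1.06 for basal and myoepithelial (7 of 15 fell, 8 adjusted over the list alone, adjusted p = 0.00129), -1.01 for pericyte and smooth muscle (5 of 10 fell, adjusted p = 0.0467), -0.34 for endothelial (5 of 13 fell, adjusted p = 0.0493), -1.47 for B cell and plasma cell (7 of 12 fell, 8 adjusted over the list alone, adjusted p = 1.37e-04), -1.11 for T cell (9 of 14 fell, adjusted p = 0.00129), -3.08 for skeletal muscle (12 of 14 fell, adjusted p = 3.97e-06) and 1.30 for ERK pathway output (12 of 17 rose, adjusted p = 1.05e-06). The milk list (-0.49, camera adjusted p = 0.791) and the luminal list (-0.22, camera adjusted p = 0.171) were not called. Among interferon response genes, 4 of 17 measured rose and 0 fell. The list median was 0.88 (camera adjusted p = 0.00586). These included Usp18 (1.69 ± 0.56, adjusted p = 0.0165).

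Among proliferation genes, 27 of 28 measured rose and 0 fell in Met tumours. The median of the list was 1.70 (camera adjusted p = 1.74e-20). All 6 of the largest decreases were in genes of skeletal muscle, such as Cox6a2 (-6.28 ± 0.69, adjusted p = 5.80e-09). Met (0.069 ± 0.59, adjusted p = 0.94), Hgf (-0.39 ± 0.51, adjusted p = 0.572) and Trp53 (0.055 ± 0.16, adjusted p = 0.811) did not pass, and of the other probes of Hgf 1 fell, by 0.76 ± 0.23 (adjusted p = 0.00745).

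The 7918 genes that passed were 3770 higher and 4148 lower (8 against 11). With slide as a random block the count was 7957, and 6157 and 6062 with scan date and scan period as a block. Within scan period 1 (8 against 5) it was 3701 and within scan date 1 (2 against 2) 414. Without the pooled glands, which leaves the same 5, it was 4526. The other scan dates of period 1 held 1 normal gland each. Within scan period 1 the medians were -1.52 for EMT transcription factors (-1.41 with the date and -1.5 with the period as a block), 0.97 for interferon response and 1.57 for proliferation. The deposited values gave 5439 higher and 3789 lower genes.

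MetTrp53 tumours were set against normal glands to describe tumours with both changes. Claudins and epithelial adhesion genes were lower in them, and Met with its chromosomal neighbours was higher. Met rose by 3.36 ± 0.51 (adjusted p = 8.19e-07), a fold of 10.3. Among Met and the genes next to it, 11 of 14 measured rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 2.33 on the log2 scale (camera adjusted p = 2.26e-05). They included Tes (4.36 ± 0.62, adjusted p = 2.64e-07). Cftr, in the same stretch, was not well above background in any normal gland, and it was at least 6.39-fold higher in the tumours (adjusted p = 4.87e-05). Among tight junction and claudin genes, 10 of 14 measured fell and 0 rose (11 and 0 adjusted over the list alone). All members together had a median of -2.13 (camera adjusted p = 0.00578). These included Cldn7 (-4.30 ± 0.87, adjusted p = 7.30e-05), Cldn4 (-2.18 ± 0.54, adjusted p = 8.87e-04) and Cldn3 (-1.45 ± 0.34, adjusted p = 4.81e-04). Among genes of epithelial adhesion and identity, 20 of 24 measured fell and 0 rose. For the list as a whole the median was -2.33 (camera adjusted p = 6.20e-05). They included Krt19 (-4.33 ± 0.95, adjusted p = 2.25e-04) and Epcam (-4.21 ± 0.91, adjusted p = 1.84e-04). Cldn1 (-0.43 ± 0.47, adjusted p = 0.461) and Cdh1 (-0.63 ± 0.52, adjusted p = 0.312) did not pass.

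Among mesenchymal genes, 9 of 18 measured rose and 0 fell in MetTrp53 tumours. The median log2 fold change was 0.76 (camera adjusted p = 0.00528). Vim (1.03 ± 0.64, adjusted p = 0.17), Twist1 (1.01 ± 0.52, adjusted p = 0.0964) and Trp53 (-0.13 ± 0.14, adjusted p = 0.457) did not pass, and Hgf (1.07 ± 0.45, adjusted p = 0.0419) did, though not with scan date or period as a block, at 1.01 (adjusted p = 0.0507) and 0.93 (adjusted p = 0.0583). Of its other probes 1 rose, by 0.96 ± 0.35 (adjusted p = 0.0207), 1 fell, by 0.58 ± 0.20 (adjusted p = 0.0126), and 1 did not pass, at -0.20 ± 0.14 (adjusted p = 0.237), so its direction depended on the probe. The largest increase was that of Prl2c3 (7.47 ± 1.05, adjusted p = 1.94e-07). The largest decreases were in fat and muscle, with Cd36 (-6.32 ± 0.60, adjusted p = 3.93e-11) and Actn3 (-6.15 ± 0.61, adjusted p = 1.16e-10). Medians of the other called lists were 2.32 for proliferation (28 of 28 rose, adjusted p = 2.01e-25), 0.73 for ERK pathway output (9 of 17 rose and 2 fell, adjusted p = 0.00305), -3.41 for adipocyte (16 of 16 fell, adjusted p = 2.18e-08), -2.89 for skeletal muscle (14 of 14 fell, adjusted p = 3.89e-05), -1.76 for basal and myoepithelial (14 of 15 fell, adjusted p = 1.10e-04), -1.82 for luminal (1 of 15 rose and 12 fell, 1 and 13 adjusted over the list alone, adjusted p = 0.00317), -2.11 for milk (8 of 11 fell, adjusted p = 0.00528), -1.62 for pericyte and smooth muscle (7 of 10 fell, adjusted p = 0.00528), -1.29 for B cell and plasma cell (2 of 12 rose and 9 fell, 2 and 10 adjusted over the list alone, adjusted p = 0.00367) and -0.85 for T cell (10 of 14 fell, adjusted p = 0.00528), so a different mix of cells may account for part of the differences.

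A total of 10977 genes passed, 4836 higher and 6141 lower (14 against 11). The counts were 11226 with slide, 11288 with scan date and 11386 with scan period as a block, 9918 within period 1 and 8528 within period 2. Within scan dates 1 and 6, the others having fewer than 2 of 1 group, they were 4222 and 4963. The claudin list's median was -2.53 with scan date and -2.40 with scan period as a block, -2.83 within period 1 and -1.47 within period 2. For Met neighbours the values in the same order were 2.16, 2.18, 2.38 and 1.83. Median centring gave 6709 higher and 5324 lower genes.

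Trp53 tumours were compared with the same normal glands, of which 7 of 11 came from Trp53 or MetTrp53 mice. Met and its ligand both rose, Met by 2.40 ± 0.59 (adjusted p = 0.00109) and Hgf by 2.89 ± 0.51 (adjusted p = 1.86e-05), folds of 5.28 and 7.42. The other probes of Hgf rose by 2.26 ± 0.40 (adjusted p = 2.21e-05), 0.59 ± 0.23 (adjusted p = 0.0337) and 0.55 ± 0.16 (adjusted p = 0.00705). Among tight junction and claudin genes, 9 of 14 measured fell and 0 rose. Their median log2 fold change was -1.95 (camera adjusted p = 0.0124). These included Cldn7 (-3.82 ± 1.0, adjusted p = 0.00201), Cldn4 (-2.46 ± 0.62, adjusted p = 0.00153) and Cldn3 (-2.02 ± 0.39, adjusted p = 6.79e-05). Among genes of epithelial adhesion and identity, 18 of 24 measured fell and 0 rose. As a list they had a median of -2.04 (camera adjusted p = 1.52e-04). They included Krt19 (-4.59 ± 1.10, adjusted p = 8.49e-04) and Epcam (-3.51 ± 1.05, adjusted p = 0.00653). Among mesenchymal genes, 10 of 18 measured rose and 0 fell. Across the list the median was 1.11 (camera adjusted p = 0.00121). These included Vim (2.12 ± 0.73, adjusted p = 0.0176), and Twist1 (1.65 ± 0.60, adjusted p = 0.0228) rose among the EMT transcription factors. Among Met and the genes next to it, 5 of 14 measured rose and 0 fell. The list had a median log2 fold change of 0.81 (camera adjusted p = 0.0407). They included Tfec (1.42 ± 0.39, adjusted p = 0.00312). Cldn1 (-0.011 ± 0.55, adjusted p = 0.99), Cdh1 (-1.15 ± 0.60, adjusted p = 0.12) and Trp53 (0.034 ± 0.16, adjusted p = 0.882) did not pass.

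The 6 largest increases in Trp53 tumours included Prl2c3 (5.73 ± 1.21, adjusted p = 1.99e-04) and Cdkn2a (4.45 ± 0.40, adjusted p = 3.21e-11). Muscle genes held 5 of the 6 largest decreases. Medians of the other called lists were 1.98 for proliferation (28 of 28 rose, adjusted p = 9.39e-26), 0.75 for ERK pathway output (10 of 17 rose, adjusted p = 1.28e-04), -3.34 for adipocyte (16 of 16 fell, adjusted p = 3.76e-09), -3.43 for skeletal muscle (14 of 14 fell, adjusted p = 1.10e-06), -1.99 for basal and myoepithelial (14 of 15 fell, adjusted p = 2.51e-05), -1.61 for luminal (1 of 15 rose and 11 fell, 1 and 12 adjusted over the list alone, adjusted p = 0.00162), -2.58 for milk (10 of 11 fell, 11 adjusted over the list alone, adjusted p = 9.28e-04), -1.60 for pericyte and smooth muscle (6 of 10 fell, adjusted p = 9.28e-04), -0.55 for endothelial (8 of 13 fell, adjusted p = 0.00565), -0.88 for B cell and plasma cell (1 of 12 rose and 6 fell, adjusted p = 0.00513) and -1.24 for T cell (10 of 14 fell, adjusted p = 0.00109), which leaves a different mix of cells open here too.

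Here 8978 genes passed, 3977 higher and 5001 lower (8 against 11). The count was 8763 with slide, 5748 with scan date and 6771 with scan period as a block, 6943 within period 2 (5 against 6) and 4750 within scan date 5 (4 against 3). The claudin list's median was -1.13 with scan date and -1.5 with scan period as a block, and -1.15 within period 2. For mesenchymal genes these were 1.07, 1.04 and 1.04. Median centring gave 5518 higher and 4048 lower genes.

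MetTrp53 and Met tumours were compared to ask what the conditional Trp53 allele and Cre added to the transgene. All 8 Met tumours came from mice that had borne litters and 10 of 14 MetTrp53 tumours from mice that had not, so genotype went with parity. MetTrp53 tumours had lower expression of claudins and epithelial adhesion genes and higher expression of mesenchymal genes. Among tight junction and claudin genes, 13 of 14 measured fell and 0 rose (14 and 0 adjusted over the list alone). Together they had a median of -2.93 (camera adjusted p = 6.27e-07). Cldn7 fell by 4.37 ± 0.95 (adjusted p = 4.95e-04), a fold of 20.7, with Cldn8 (-4.13 ± 1.0, adjusted p = 0.00137), Cldn1 (-3.20 ± 0.52, adjusted p = 2.43e-05), Cldn4 (-2.91 ± 0.60, adjusted p = 2.65e-04) and Cldn3 (-1.16 ± 0.37, adjusted p = 0.014) and Marveld3 (-4.11 ± 0.81, adjusted p = 1.79e-04). Among genes of epithelial adhesion and identity, 23 of 24 measured fell and 0 rose (24 and 0 adjusted over the list alone). Over all members the median was -2.65 (camera adjusted p = 9.57e-10). These included the adhesion proteins Epcam (-4.37 ± 1.0, adjusted p = 8.26e-04) and Cdh1 (-2.06 ± 0.57, adjusted p = 0.00452) and the splicing factors of epithelial cells Esrp1 (-3.75 ± 0.79, adjusted p = 3.66e-04) and Esrp2 (-3.64 ± 0.73, adjusted p = 2.03e-04).

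Among EMT transcription factors, 8 of 9 measured rose and 0 fell in MetTrp53 tumours. The list median was 2.22 (camera adjusted p = 6.06e-06). These included Twist1 (2.99 ± 0.57, adjusted p = 1.24e-04), Prrx1 (2.74 ± 0.48, adjusted p = 5.77e-05) and Twist2 (2.46 ± 0.61, adjusted p = 0.00177). Among mesenchymal genes, 16 of 18 measured rose and 0 fell (17 and 0 adjusted over the list alone). The median of the list was 1.85 (camera adjusted p = 6.51e-08). They included S100a4 (3.96 ± 0.71, adjusted p = 6.31e-05) and Vim (3.29 ± 0.70, adjusted p = 3.84e-04) and the protease Mmp3 (3.07 ± 0.78, adjusted p = 0.00211). Markers of stromal cells moved with them. Among genes of fibroblasts and matrix, 13 of 16 measured rose and 0 fell (15 and 0 adjusted over the list alone). Their median was 1.69 on the log2 scale (camera adjusted p = 3.03e-06). These included Pdgfra (2.80 ± 0.66, adjusted p = 0.0011). Medians of further called lists were 0.44 for macrophage (6 of 15 rose and 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.0259), 1.16 for Wnt pathway targets (8 of 16 rose and 1 fell, 9 and 1 adjusted over the list alone, adjusted p = 0.036), -0.82 for adipocyte (5 of 16 fell, 4 adjusted over the list alone, adjusted p = 0.036), -0.82 for luminal (1 of 15 rose and 7 fell, adjusted p = 0.0402) and -2.08 for milk (6 of 11 fell, 8 adjusted over the list alone, adjusted p = 0.00108), so a different mix of cells may account for part of the difference.

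Met and its neighbours were higher in MetTrp53 tumours. Met rose by 3.30 ± 0.56 (adjusted p = 4.00e-05) at the probe used, a fold of 9.82, and by 2.80 ± 0.52 (adjusted p = 1.06e-04) at 17513642, while the probe at 17493755 had a difference of 0.91 ± 0.45 (adjusted p = 0.117). Counting Met itself, 12 of 14 measured genes of the stretch rose and 0 fell. All members together had a median of 2.27 (camera adjusted p = 3.43e-07). They included Cav1 (4.29 ± 0.80, adjusted p = 9.43e-05) and Tes (3.23 ± 0.69, adjusted p = 3.86e-04). Hgf rose by 1.46 ± 0.49 (adjusted p = 0.0175) and at 1 other probe, by 1.09 ± 0.39 (adjusted p = 0.0245), and did not pass at the remaining 2. Among genes that p53 activates, 11 of 28 measured fell and 1 rose (11 and 2 adjusted over the list alone). For the list as a whole the median was -0.24 (camera adjusted p = 0.0384). These included Psrc1 (-3.77 ± 0.45, adjusted p = 8.29e-07) and Perp (-2.33 ± 0.55, adjusted p = 0.00108) and the cell cycle inhibitor Cdkn1a (-1.47 ± 0.29, adjusted p = 1.71e-04). Among interferon response genes, 12 of 17 measured fell and 0 rose (13 and 0 adjusted over the list alone). The median log2 fold change was -1.32 (camera adjusted p = 1.34e-04). They included Usp18 (-2.26 ± 0.54, adjusted p = 0.00117). Among proliferation genes, 14 of 28 measured rose and 0 fell (17 and 0 adjusted over the list alone). Their median log2 fold change was 0.65 (camera adjusted p = 3.65e-06). The difference was -0.18 ± 0.15 (adjusted p = 0.372) for the used probe of Trp53, and the other probe fell by 1.46 ± 0.29 (adjusted p = 1.82e-04).

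Between these tumours 7575 genes passed, 3422 higher and 4153 lower in MetTrp53 tumours (14 against 8), and median centring turned the balance, to 2962 and 2434. With slide as a random block there were 7828, with scan date and scan period as a block 6954 and 7609, and within period 1 (10 against 8) 6136. Within scan dates 1 and 2 (3 against 2 each) there were 1492 and 1509, and within scan date 3 limma called 0, with 483 at an unadjusted p under 0.05. Within period 1 the medians were -2.74 for the claudin, 2.03 for the EMT transcription factor and 2.40 for the Met neighbour list. With scan date as a block they were -2.62, 1.91 and 2.31, and with scan period -2.60, 1.99 and 2.37. With pathology as a covariate 1106 genes passed, 36 of 47 genes of the naming rule lost their call, among them Cldn7, Cdh1, Twist1 and Vim, and the adipocyte, luminal, macrophage, milk and Wnt lists lost theirs. The medians were then -1.18 for the claudin, -0.98 for the epithelial, 1.0 for the EMT and 0.96 for the mesenchymal list, so part of the difference went with pathology. With parity as a covariate 5004 passed, and the same medians were -2.61, -2.46, 2.02 and 1.51; Cldn3 (-1.07) and the p53 target (-0.23) and Wnt target (0.97, adjusted p = 0.107) lists no longer passed. Within scan date 3, which held the 1 spindloid Met tumour, the claudin, epithelial, luminal and adipocyte lists and Cldn7, Cldn8, Cdh1, Epcam, Esrp1, Esrp2, Marveld3, Ccbe1, Hgf and Twist2 turned their direction, as the adipocyte list did within scan date 1.

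**Figure D2:**
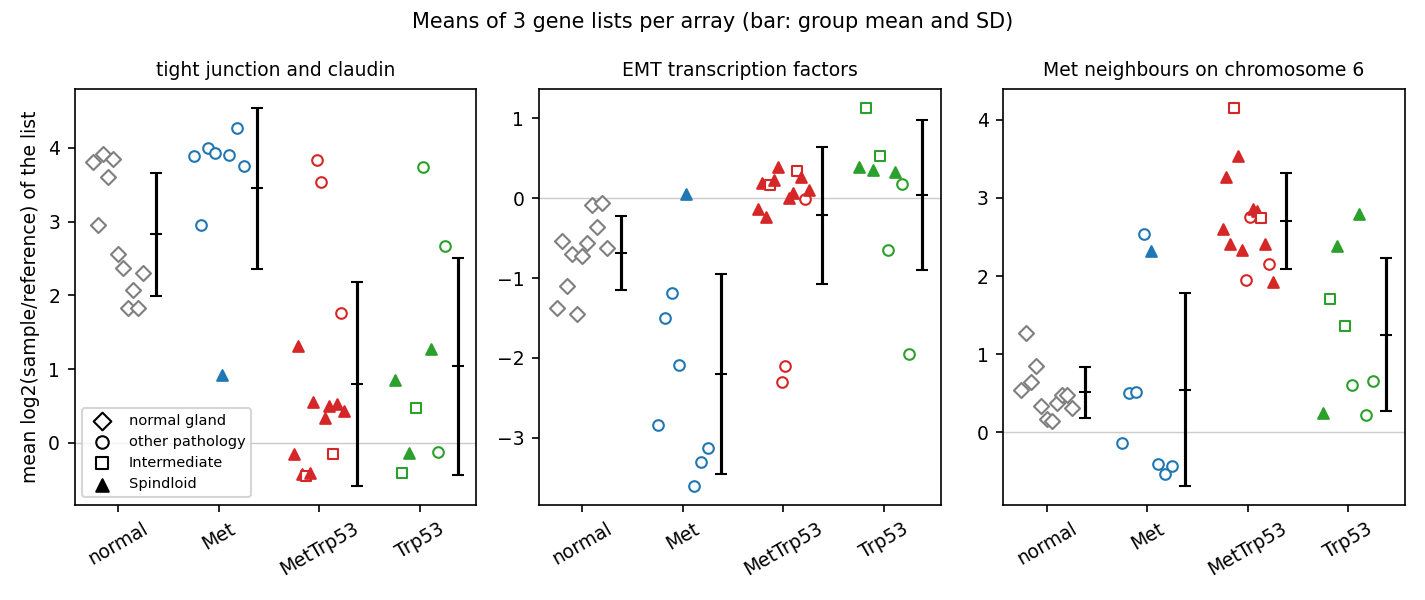
Mean log2 ratio of sample over reference for 3 gene lists on each array (points, 11 normal glands, 8 Met, 14 MetTrp53 and 8 Trp53 tumours), with the group mean and SD as a bar. The 1 spindloid Met tumour has a claudin mean of 0.92, below the other 7 Met tumours at 2.96 to 4.27.

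MetTrp53 and Trp53 tumours were compared to ask what the transgene added to the Trp53 allele and Cre. Genes next to Met on chromosome 6 were higher in MetTrp53 tumours, and no claudin named here passed. Among genes next to Met, 5 of 14 measured rose and 0 fell (6 and 0 adjusted over the list alone). As a list they had a median of 1.26 (camera adjusted p = 1.24e-06). They included Tes (3.66 ± 0.69, adjusted p = 0.0217), Cav2 (2.21 ± 0.62, adjusted p = 0.0415), Mdfic (1.98 ± 0.54, adjusted p = 0.0385), Lsm8 (1.95 ± 0.53, adjusted p = 0.0366) and Capza2 (1.77 ± 0.46, adjusted p = 0.0344). These 5 and the neurofilament Nefm (1.99 ± 0.54, adjusted p = 0.039) were the 6 largest increases, with accessions and clones left out. Hgf fell by 1.82 ± 0.49 (adjusted p = 0.0369), a call that ended with slide, scan date or period as a block, at -1.78 (adjusted p = 0.0796), -1.06 (adjusted p = 0.87) and -1.38 (adjusted p = 0.999). Met (0.96 ± 0.56, adjusted p = 0.346), Cldn1 (-0.42 ± 0.52, adjusted p = 0.704), Cldn3 (0.57 ± 0.37, adjusted p = 0.412), Cldn4 (0.28 ± 0.60, adjusted p = 0.841) and Cldn7 (-0.47 ± 0.95, adjusted p = 0.832) did not pass, nor did Cdh1 (0.51 ± 0.57, adjusted p = 0.667), Vim (-1.09 ± 0.70, adjusted p = 0.399), Twist1 (-0.64 ± 0.57, adjusted p = 0.569) and Trp53 (-0.16 ± 0.15, adjusted p = 0.60). Met rose at its probe at 17493755, by 1.75 ± 0.45 (adjusted p = 0.032), and not at 17513642, 0.88 ± 0.52 (adjusted p = 0.34).

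Further decreases in MetTrp53 against Trp53 tumours were Aldh3a1 (-2.23 ± 0.54, adjusted p = 0.0274) and the housekeeping genes Eef1a1 (-1.77 ± 0.48, adjusted p = 0.0387) and Tpt1 (-1.66 ± 0.43, adjusted p = 0.0344), the 2 genes that were higher in scan period 2. Eef1a1 turned its direction with scan date or period as a block, to 0.52 and 0.13. Among endothelial genes, 0 of 13 measured rose and 0 fell. Across the list the median was 0.39 (camera adjusted p = 0.00699). It turned to -0.21 with scan date and -0.15 with scan period as a block, and -0.088 within period 2, as it did after scaling between arrays (-0.034). The Met neighbour list kept medians of 1.12, 1.06 and 0.97.

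In this comparison 610 genes passed, 165 higher and 445 lower in MetTrp53 tumours (14 against 8), and the count was not stable. It was 318 with the animal as a random block, and limma called 0 with 1 tumour per animal (3412 at an unadjusted p under 0.05). Processed intensities gave 147 and 232, and median centring 2 and 0. The fit in limma called 0 genes with slide as a random block, 0 with scan date and 0 with scan period as a block, and 0 within period 2. At an unadjusted p under 0.05 these had 3388, 1133, 790 and 777 genes. Leaving out 1 tumour gave from 2 (without Trp53 tumour 8) to 1366 (without MetTrp53 tumour 11), and leaving out the 3 Trp53 tumours of period 3 gave 2.

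**Figure D3:**
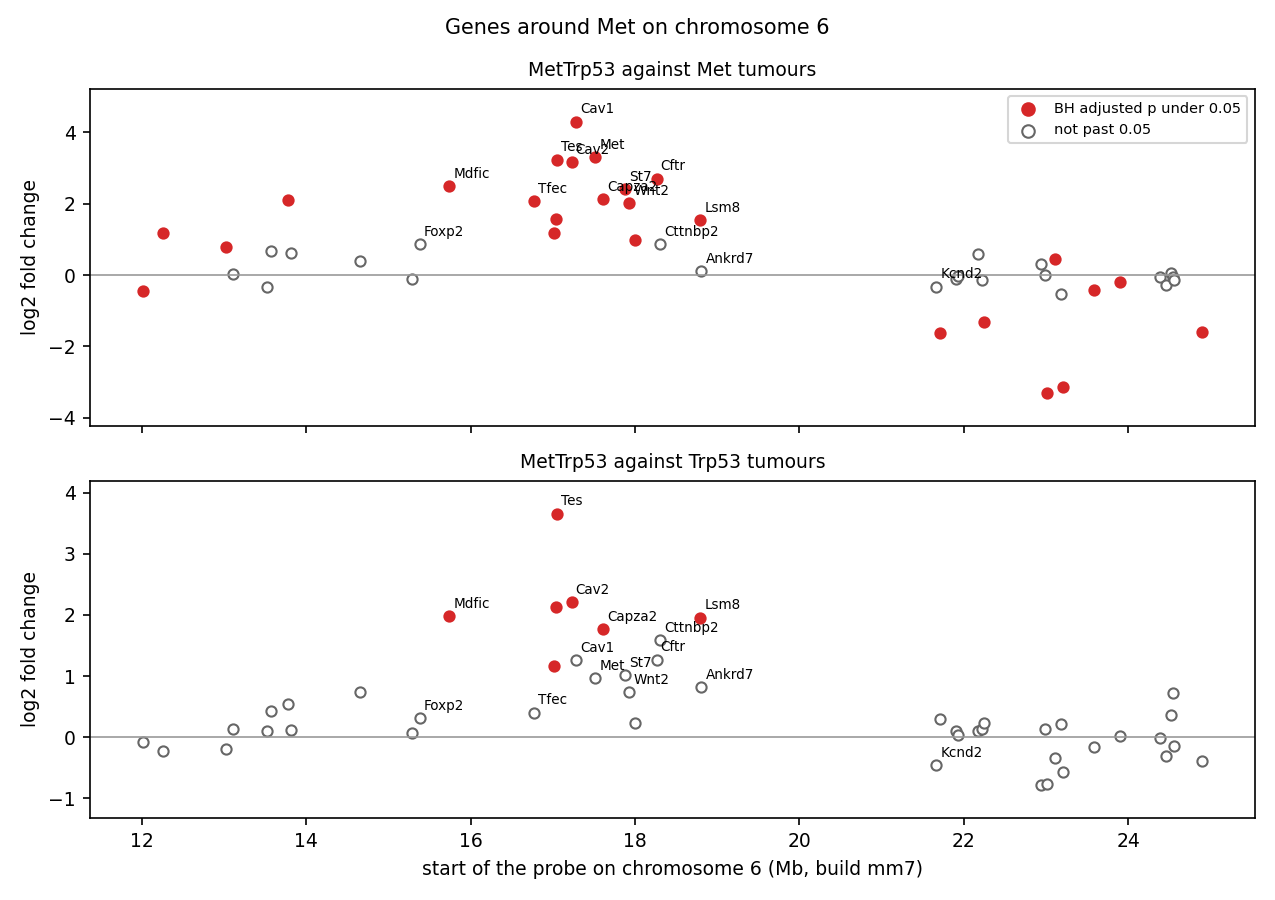
Log2 fold change of each tested gene against the start of its probe on chromosome 6 (Mb, build mm7), for MetTrp53 against Met tumours (14 and 8) and against Trp53 tumours (14 and 8), with genes past an adjusted p of 0.05 filled. The 11 genes from Gm4876 to Cftr, centred on Met, have a median of 2.41 against Met tumours.

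Trp53 and Met tumours were compared to set the 2 single changes side by side. Trp53 tumours had lower claudins and epithelial adhesion and higher mesenchymal genes, as MetTrp53 tumours had. Among tight junction and claudin genes, 13 of 14 measured fell and 0 rose. The list had a median log2 fold change of -2.47 (camera adjusted p = 4.92e-05). These included Cldn7 (-3.90 ± 1.07, adjusted p = 0.00423), Cldn4 (-3.19 ± 0.67, adjusted p = 3.79e-04), Cldn1 (-2.78 ± 0.59, adjusted p = 4.14e-04) and Cldn3 (-1.73 ± 0.42, adjusted p = 0.00159). Among genes of epithelial adhesion and identity, 21 of 24 measured fell and 0 rose (22 and 0 adjusted over the list alone). Together they had a median of -2.60 (camera adjusted p = 3.95e-07). They included Epcam (-3.67 ± 1.13, adjusted p = 0.00966) and Cdh1 (-2.57 ± 0.65, adjusted p = 0.00197). Among EMT transcription factors, 9 of 9 measured rose and 0 fell. Over all members the median was 2.37 (camera adjusted p = 2.49e-05). These included Twist1 (3.63 ± 0.64, adjusted p = 6.21e-05) and Twist2 (2.83 ± 0.69, adjusted p = 0.00155). Among mesenchymal genes, 15 of 18 measured rose and 0 fell (16 and 0 adjusted over the list alone). The list median was 2.0 (camera adjusted p = 3.95e-07). They included S100a4 (4.52 ± 0.80, adjusted p = 6.10e-05) and Vim (4.38 ± 0.79, adjusted p = 7.64e-05). Met and Hgf rose by 2.33 ± 0.63 (adjusted p = 0.00386) and 3.29 ± 0.55 (adjusted p = 3.64e-05), and Trp53 (-0.021 ± 0.17, adjusted p = 0.934) did not pass. The other probe of Trp53 fell by 0.89 ± 0.32 (adjusted p = 0.0266). At the other probes of Met the difference was 1.92 ± 0.59 (adjusted p = 0.00939) (17513642) and -0.85 ± 0.51 (adjusted p = 0.189) (17493755), so its direction depended on the probe. With scan date as a block 30 of 31 genes of the naming rule lost their call, Met (2.97, adjusted p = 0.117) and Hgf among them, and with scan period 22 did, including the claudins named here, Epcam, Cdh1, Twist1 and Vim.

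Medians of the other called lists in Trp53 against Met tumours were 1.36 for fibroblast and matrix (7 of 16 rose, 10 adjusted over the list alone, adjusted p = 3.70e-04), -2.45 for milk (10 of 11 fell, 11 adjusted over the list alone, adjusted p = 8.81e-04), -1.03 for interferon response (9 of 17 fell, 10 adjusted over the list alone, adjusted p = 0.00464) and 0.30 for proliferation (9 of 28 rose, adjusted p = 0.00653). That of proliferation turned after scaling between arrays, to -9.89e-04. The p53 target list was not called (-0.17, camera adjusted p = 0.103): 11 of 28 fell and 1 rose, and Psrc1 (-3.64 ± 0.51, adjusted p = 4.69e-06) was among those that fell.

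The 8262 genes past the threshold were 3776 higher and 4486 lower in Trp53 tumours (8 against 8), and median centring turned the balance, to 3125 and 2597. No scan period or date held both groups, so no value within a batch can be had, and a blocked fit compares them only through the groups they share with others. The count was 7422 with slide as a random block, 510 with scan period and 6 with scan date as a block. Of the genes called, 2917 and 2178 kept their sign with an unadjusted p under 0.05. The list medians were -1.71 for claudins, -2.20 for epithelial adhesion, 2.18 for EMT transcription factors and 1.71 for mesenchymal genes with scan period as a block. With scan date they were -1.26, -1.53, 1.78 and 1.71. With pathology as a covariate 4840 genes passed, and with parity 5325. In the parity fit the 3 Trp53 tumours of period 3, whose parity was not given, had a level of their own, and leaving them out gave 6954 without a covariate.

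Pathology was compared between the genotypes. Spindloid tumours, which are built of spindle-shaped cells, made up 9 of 14 MetTrp53, 3 of 8 Trp53 and 1 of 8 Met tumours, while 4 of 8 Met tumours were solid nodular carcinomas. For MetTrp53 against Met tumours, Fisher's exact test, 2-sided, gave p = 0.031, and adjusted p = 0.0929 over the 3 pairs, which did not pass. Counting the 4 Intermediate tumours as spindloid gave 11 of 14 against 1 of 8, with exact p = 0.00619 and adjusted p = 0.0186. The other 2 pairs had exact p of 0.569 (Trp53 against Met, adjusted p = 0.569) and 0.378 (MetTrp53 against Trp53, adjusted p = 0.567).

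Spindloid tumours were compared with tumours of other pathology (13 against 13, the 4 Intermediate tumours left out), with genotype in the fit, to ask which changes went with pathology itself. Claudin and epithelial genes were lower in spindloid tumours, and EMT transcription factors were higher. Among tight junction and claudin genes, 12 of 14 measured fell and 0 rose. The median of the list was -2.52 (camera adjusted p = 1.29e-12). These included Marveld3 (-4.06 ± 0.54, adjusted p = 5.67e-05), Cldn7 (-3.73 ± 0.87, adjusted p = 0.00524), Cldn4 (-2.04 ± 0.53, adjusted p = 0.011) and Cldn1 (-1.92 ± 0.50, adjusted p = 0.0101), while Cldn3 (-0.54 ± 0.39, adjusted p = 0.414) did not pass. Among genes of epithelial adhesion and identity, 23 of 24 measured fell and 0 rose (24 and 0 adjusted over the list alone). Their median was -2.53 on the log2 scale (camera adjusted p = 5.55e-19). They included Epcam (-4.26 ± 0.90, adjusted p = 0.00249), Esrp2 (-3.79 ± 0.46, adjusted p = 2.06e-05) and Cdh1 (-1.46 ± 0.49, adjusted p = 0.0465). Among EMT transcription factors, 7 of 9 measured rose and 0 fell (8 and 0 adjusted over the list alone). All members together had a median of 1.60 (camera adjusted p = 5.97e-07). These included Twist2 (2.52 ± 0.56, adjusted p = 0.00373), Prrx1 (2.32 ± 0.38, adjusted p = 3.62e-04) and Twist1 (2.16 ± 0.52, adjusted p = 0.00639). Among mesenchymal genes, 7 of 18 measured rose and 0 fell (12 and 0 adjusted over the list alone). For the list as a whole the median was 1.30 (camera adjusted p = 2.58e-07). They included S100a4 (3.14 ± 0.49, adjusted p = 2.22e-04), Mmp3 (2.91 ± 0.80, adjusted p = 0.0157) and Vim (2.41 ± 0.57, adjusted p = 0.00598).

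Markers of other cell types moved with these. Medians of the other called lists in spindloid tumours were 1.14 for fibroblast and matrix (4 of 16 rose, 7 adjusted over the list alone, adjusted p = 1.56e-05), 0.57 for macrophage (4 of 15 rose, 7 adjusted over the list alone, adjusted p = 0.00193), 0.90 for neutrophil (2 of 10 rose, 3 adjusted over the list alone, adjusted p = 0.0148), 0.33 for endothelial (2 of 13 rose, 4 adjusted over the list alone, adjusted p = 0.00193), -0.71 for adipocyte (1 of 16 fell, adjusted p = 0.0446), -0.65 for luminal (2 of 15 rose and 4 fell, 2 and 7 adjusted over the list alone, adjusted p = 0.0411), -1.49 for milk (4 of 11 fell, adjusted p = 0.00193), -1.09 for interferon response (3 of 17 fell, 9 adjusted over the list alone, adjusted p = 1.38e-04) and 0.85 for Wnt pathway targets (8 of 16 rose and 1 fell, adjusted p = 0.00621), so a different mix of cells may account for part of the difference. The median of the Met neighbour list was 1.03 (3 of 14 rose, 7 adjusted over the list alone, adjusted p = 0.00193). Met (1.54 ± 0.56, adjusted p = 0.0679), Hgf (1.34 ± 0.53, adjusted p = 0.0974) and Trp53 (0.13 ± 0.16, adjusted p = 0.642) did not pass. Among proliferation genes, 0 of 28 measured rose and 0 fell, with a median of 0.018.

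Of the genes tested, 2964 passed, 1527 higher and 1437 lower in spindloid tumours. Median centring gave 1092 and 1844. The count was 2970 with slide, 3118 with scan date and 3976 with scan period as a block and 4210 within period 1. Within scan date 3 it was 462. The fit called 0 genes within period 2 and 0 within scan date 6, with 2210 and 2858 at an unadjusted p under 0.05. The claudin median was -2.46 with scan date, -2.60 with scan period as a block, -3.20 within period 1 and -2.20 within period 2. For EMT transcription factors these were 1.8, 1.58, 2.45 and 0.72. Within period 2 the fibroblast, endothelial, interferon and Wnt lists turned, to -0.13, -0.13, 0.15 and -0.078, and within scan date 6 Cdh1, Cldn1, Mmp3, Prrx1 and Twist2 turned their direction. Without the 1 spindloid Met tumour the count was 1384, without MetTrp53 tumour 7 1883, in MetTrp53 tumours alone 1841, with Intermediate tumours counted as other 639, and without genotype in the fit 6616.

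Whether the spindloid difference depended on genotype was tested as an interaction between MetTrp53 and Trp53 tumours. Met alone passed, at 1 of its 3 probes. In MetTrp53 tumours its log2 ratio was 4.27 ± 0.19 (SD, n = 9) in spindloid and 4.38 ± 0.36 (n = 3) in other tumours. In Trp53 tumours it was 4.35 ± 0.46 (n = 3) in spindloid and 1.63 ± 0.51 (n = 3) in other tumours, the last from 2 mice, 1 of which also gave a spindloid tumour. The difference of the 2 spindloid effects was -2.83 ± 0.34 (adjusted p = 0.00646), and -2.20 (adjusted p = 0.0795) with scan date as a block, which did not pass. At 17513642 and 17493755 the values were -1.04 ± 0.93 (adjusted p = 0.714) and -3.23 ± 0.60 (adjusted p = 0.151). It was -2.88 (adjusted p = 0.00402) with the animal as a random block (estimated correlation -0.11) and -2.67 with 1 tumour per animal. The latter leaves 1 other Trp53 tumour, whose spread is taken from the other tumours, so it cannot show that the difference holds. The values for Cldn7 -4.93 ± 2.06, Hgf 1.96 ± 1.25, Cldn3 -1.15 ± 1.0, Twist1 0.89 ± 0.88, Cldn4 -0.39 ± 1.32, Cdh1 0.63 ± 1.32, Vim 0.55 ± 1.21, Trp53 -0.29 ± 0.27 and Cldn1 -0.031 ± 1.32 did not pass (adjusted p from 0.444 to 0.996). Camera called 7 lists: epithelial adhesion and identity (-1.70, adjusted p = 0.00396), ERK pathway output (-0.60, adjusted p = 0.00785), hypoxia and glycolysis (-1.03, adjusted p = 6.79e-04), interferon response (-1.26, adjusted p = 0.00284), Met neighbours on chromosome 6 (-0.75, adjusted p = 0.0145), proliferation (0.29, adjusted p = 0.0135), skeletal muscle (2.69, adjusted p = 6.79e-04). With an estimated correlation their adjusted p values ran from 0.443 to 0.999. Among these lists, only Met itself passed among the Met neighbours, and of the others 1 ERK gene fell when adjusted over the list alone.

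In limma 1 of 20676 genes passed in the interaction, with 2054 at an unadjusted p under 0.05. The count was 2 with slide as a random block, 125 with scan date and 1 with scan period as a block. It was 0 after scaling between arrays and 0 with the mean of a gene's probes, with 2285 and 2079 at an unadjusted p under 0.05. With 1 tumour per animal it was 37, which rests on that 1 tumour. No scan date or period held at least 2 tumours of both pathologies of both genotypes. The interferon list turned its direction with scan date as a block, to 0.71, as did the epithelial and proliferation lists with 1 tumour per animal, to 0.18 and -0.17.

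Normal glands of mice that had borne litters were compared with those of mice that had not (6 multiparous against 5 nulliparous). No single gene passed in limma, with 658 at an unadjusted p under 0.05. Camera called 6 lists with a positive median: milk (0.76, adjusted p = 9.44e-08), tight junction and claudin (0.54, adjusted p = 1.49e-05), epithelial adhesion and identity (0.42, adjusted p = 1.06e-04), basal and myoepithelial (0.30, adjusted p = 0.00462), skeletal muscle (0.34, adjusted p = 5.63e-04), adipocyte (0.15, adjusted p = 0.0199). It called 8 with a negative median: fibroblast and matrix (-0.62, adjusted p = 9.44e-08), mesenchymal genes (-0.44, adjusted p = 2.16e-05), EMT transcription factors (-0.42, adjusted p = 2.88e-05), Wnt pathway targets (-0.52, adjusted p = 4.63e-04), growth factor receptors (-0.25, adjusted p = 0.00636), hypoxia and glycolysis (-0.32, adjusted p = 0.0098), ERK pathway output (-0.22, adjusted p = 0.0271), Met neighbours on chromosome 6 (-0.087, adjusted p = 0.0455). With an estimated correlation their adjusted p values ran from 0.086 to 0.473, and 0 members of any of them passed, also when adjusted over the list alone. The log2 fold changes were Met -1.08 ± 0.56, Vim -1.06 ± 0.76, Cldn7 0.66 ± 0.34, Twist1 -0.64 ± 0.41, Cldn3 0.37 ± 0.16, Cldn1 0.27 ± 0.46, Trp53 0.21 ± 0.21, Hgf -0.18 ± 0.22, Cldn4 0.10 ± 0.58 and Cdh1 0.048 ± 0.84, with adjusted p = 1.0 for each. With scan date as a block limma called 0 genes and with scan period 1, and 0 and 0 within periods 1 and 2. At an unadjusted p under 0.05 the counts were 1879, 1183, 690 and 1487. The milk median was 1.03 and 0.73 with these blocks, -0.048 within period 1, where it turned, and 1.30 within period 2. The fibroblast median was -0.71, -0.58, -0.43 and -0.67.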

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

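The tests of the Met probes and the scan period block were chosen after the result was seen. A sample counted as far from its group when its gap to the next sample exceeded Dixon's 95% critical value. Of 78 groups of 8 values, 12 held such a sample, and chance gives about 1 in 20.

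Met tumour 5, the 1 spindloid Met tumour, lay far from the other 7 Met tumours in 7 measures (log2 ratio, with the range of the others): Hgf 2.82 against -0.98 to 0.46, Cldn1 2.06 against 3.89 to 5.19, Cldn7 -0.58 against 2.75 to 4.13 and Cdh1 2.81 against 4.04 to 5.01. The others were the means of the epithelial list, 0.53 against 2.91 to 3.35, the milk list, 3.50 against 4.56 to 5.40, and the claudin list, 0.92 against 2.96 to 4.27. Met tumour 3 lay above the others in the B cell list, -0.70 against -1.96 to -1.43, and the T cell list, 0.49 against -0.78 to -0.33. Trp53 tumour 6 was high in the B cell list, 0.56 against -1.85 to -0.94, Trp53 tumour 8 low in mesenchymal genes, -1.03 against 0.24 to 1.26, and Trp53 tumour 5 high in pericyte and smooth muscle genes, 2.50 against 0.54 to 1.24. The cause of these distances was not tested.

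The spindloid difference was not the same in MetTrp53 and Trp53 tumours for Met (-2.83, tested as an interaction), though not with scan date as a block (-2.20, adjusted p = 0.0795) or at 2 of its 3 probes. Camera called 7 lists at its preset correlation, and 0 with an estimated one (adjusted p from 0.443 to 0.999) or with fry. Their medians were -1.70 for epithelial adhesion, -0.60 for ERK output, -1.03 for hypoxia, -1.26 for interferon response, -0.75 for Met neighbours, 0.29 for proliferation and 2.69 for skeletal muscle. By random regrouping chance could not be excluded for the number of genes: 39 of 100 splits gave at least 1 gene, and the highest other gave 519. That split set the 3 Trp53 tumours of scan period 3 against 3 of period 2, which points to a structure of the samples by scan period. With scan period as a block the real count was 1.

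Chance was excluded at 1 of 100 splits, the real one, for 8 comparisons (genes called, and highest other split). Against normal glands these were 9951 and 3001 in all tumours, 7918 and 2617 in Met, 10977 and 4216 in MetTrp53 and 8978 and 1411 in Trp53 tumours. The other 4 were MetTrp53 against Met tumours 7575 and 4407, MetTrp53 against Trp53 tumours 610 and 206, Trp53 against Met tumours 8262 and 1856, spindloid against other tumours 2964 and 34. The splits ignored scan date and period, which go with group, and mice with 2 samples, so neither source is excluded. By limma MetTrp53 against Trp53 tumours had 0 genes with slide, scan date or period as a block or 1 tumour per animal. At an unadjusted p under 0.05 these had 3388, 1133, 790 and 3412. Trp53 against Met tumours had 7422, 6 and 510 with these blocks. For parity the real count was 0 (limma, 658 unadjusted), so this test could not bear on it. The highest other split, 7180, was that by scan period and pooling, a structure of the samples, and with scan period as a block parity had 1 gene.

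The first pattern is the higher expression of genes next to Met in MetTrp53 than in Met tumours. A higher share of mesenchymal cells was argued against as the whole cause: with the mesenchymal mean as a covariate the neighbours' difference went from 2.16 ± 0.39 to 1.38 ± 0.47 (permutation p = 0.00677), and that of EMT transcription factors from 1.98 to 0.28 (permutation p = 0.234). Scan period was argued against by a difference of 2.32 within period 1 (permutation p = 2.50e-04). More copies or a shared regulation of the stretch stay open, since no DNA was measured. The median of the 11-gene window on Met, 2.41, lay above 99.97% of all windows (the highest had 2.72), but it holds 9 genes of the list itself, so its rank only repeats the pattern.

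The second pattern is that Met's first probe was higher in Met tumours than normal glands and the 2 later probes were not. First minus used probe was 1.41 ± 1.97 (SD, n = 8) in Met and -1.77 ± 0.28 (n = 8) in Trp53 tumours. The gap, 3.18 (exact permutation p = 1.55e-04), may come from scan period, as they shared none. A first probe that reads another gene raised in any tumour stays open. Both probes rose in Trp53 tumours, so the difference from normal glands, -0.41 (bootstrap SE 0.17), cannot decide. A transgene transcript without the later probes' sequence may explain the pattern, and then the used probe would not read it. The transgene's sequence was not at hand, so the cause stays open. With the transgene the difference was -0.98 ± 0.53 in 14 MetTrp53 tumours, where the used probe was high, and -1.21 ± 0.53 in 7 normal glands. The 4 without, all of period 2, had -1.63 ± 0.38.

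The third pattern is the number of genes that differed between Trp53 and Met tumours, which shared no scan period. Scan period may account for part of it: with period as a block 35.3% of the called genes kept their sign and an unadjusted p under 0.05. It was argued against as the whole source of the claudin, epithelial, EMT and mesenchymal differences, since 4 of 4 medians kept at least 50% of their size (69.3%, 84.9%, 92% and 85.5%), with median gene SEs of 0.92, 1.01, 0.73 and 0.72. Pathology alone was argued against by the 79.4% of genes kept with pathology as a covariate. In the 2 groups alone genotype and scan period cannot be told apart, and through the other groups 510 single genes passed with period as a block, while 22 of 31 genes of the naming rule lost their call.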

How the results depend on the processing

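Scan period as a block, values within a period and fits without the 3 Trp53 tumours of period 3 were chosen after the data were seen, as were the animal as a block and 1 tumour per animal in the interaction. Signal over background limits what can be tested to the 20678 genes above background on at least 8 arrays. Counts in tumours against normal glands stayed within 1.5 times under all alternatives run, and no called list there turned. Against normal glands, leaving out 1 array gave 9429 to 10142 genes for all tumours and 7237 to 8291 for Met tumours. For MetTrp53 and Trp53 tumours these were 10520 to 11134 and 8193 to 9057. Against Met tumours they were 6394 to 8537 for MetTrp53 and 7395 to 8969 for Trp53 tumours. For parity they were 0 to 0. For spindloid tumours the range was 1384 (without Met tumour 5) to 3717, and 1883 without MetTrp53 tumour 7. Median centring or the deposited values moved the median gene by more than 0.1 against normal glands: 0.104 in all tumours and 0.117 in Met tumours (deposited), 0.119 and 0.111 in MetTrp53 tumours and 0.117 in Trp53 tumours (centring).

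Fits within 1 batch, on fewer arrays, gave fewer genes except for spindloid tumours in period 1 (4210). For Met tumours against normal glands there were 414 within scan date 1, 3701 within period 1 and 4526 without pooled glands. MetTrp53 tumours against normal glands had 4222 and 4963 within dates 1 and 6, and Trp53 tumours 4750 within date 5 and 5748 with date as a block. MetTrp53 against Met tumours had 1492, 1509 and 0 within dates 1, 2 and 3 (483 at an unadjusted p under 0.05 in the last, by limma). Spindloid tumours had 462 within date 3, 0 within date 6 (2858 unadjusted) and 0 within period 2 (2210 unadjusted).

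MetTrp53 against Trp53 tumours was the comparison whose count moved under most alternatives. It had 379 genes with processed intensities, 207 with deposited values, 2965 with array weights and 318 with the animal as a block. It had 2 with median centring, 2 with parity (where the 3 Trp53 tumours of period 3, of no given parity, have their own level), 2 in a fit of these groups alone and 2 without the Trp53 tumours of period 3. It had 0 by limma with slide, 0 with scan date and 0 with scan period as a block, 0 within period 2, 0 with pathology and 0 with 1 tumour per animal (3388, 1133, 790, 777, 3673 and 3412 at an unadjusted p under 0.05). Leaving out 1 array gave 2 to 1366. The counts that moved, with the MetTrp53 tumour left out, were 198 (1), 240 (2), 279 (3), 130 (4), 273 (5), 190 (6), 290 (7), 356 (8), 214 (9), 217 (10), 1366 (11), 1080 (12), 1070 (14), and with the Trp53 tumour left out 89 (2), 321 (4), 340 (6), 197 (7), 2 (8). The cause was not tested.

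Covariates moved other counts. With parity there were 5004 genes in MetTrp53 and 5325 in Trp53 against Met tumours, the latter with the same 3 tumours set apart (6954 without them and no covariate), and with pathology 1106 and 4840. Trp53 against Met tumours had 510 with scan period and 6 with scan date as a block, where the 2 groups are compared only through others. Spindloid tumours had 6616 without genotype in the fit, 1841 in MetTrp53 tumours alone and 639 with Intermediate tumours as other. Counting these as spindloid, Fisher's exact p for MetTrp53 against Met tumours was 0.00619 (adjusted 0.0186), now under 0.05, with parity not separated from genotype. The interaction had 2 genes with processed intensities, 3 with median centring, 5 with deposited values, 2 with slide and 125 with scan date as a block, and 37 with 1 tumour per animal, where 1 arm is a single tumour. By limma it had 0 with scaling and 0 with mean of all probes (2285 and 2079 unadjusted). Leaving out 1 array gave 1 to 80, moved without MetTrp53 tumours to 2 (6), 2 (12), 63 (13) and without Trp53 tumours to 4 (1), 14 (3), 80 (5), 3 (7), 6 (8). Parity had 1 gene with scan period as a block and 1 with pooling, and with slide as a random block it was not run, since the correlation could not be estimated. The cause was not tested.

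With an estimated correlation camera called 0 lists in all 10 comparisons. With fry there were 1 list in MetTrp53 against Trp53 tumours, 7 in spindloid tumours and 0 in the interaction and in parity. Over lists, comparisons and alternatives, 11081 values kept direction and side of the threshold, 261 lost the call, 239 gained it and 19 turned. For named genes these were 11633, 681, 61 and 19. Of the genes of the model, Trp53 in tumours against normal glands gained a call with mean of all probes, -0.38 (adjusted p = 0.037). Met in Trp53 against Met tumours lost it with mean of all probes, 1.14 (adjusted p = 0.0815), with scan date as a block, 2.97 (adjusted p = 0.117), in a fit of only the groups compared, 2.33 (adjusted p = 0.0538), and with pathology, 1.48 (adjusted p = 0.0924).

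The values that turned (log2, list medians or genes) were as follows. In MetTrp53 against Met tumours within scan date 3 they were 0.096 for adipocyte (0.42 within date 1), 0.26 for epithelial, 0.28 for luminal and 0.21 for claudin lists, and Ccbe1 -0.40, Cdh1 0.38, Cldn7 0.19, Cldn8 1.54, Epcam 0.59, Esrp1 0.32, Esrp2 0.59, Hgf -0.47, Marveld3 0.23, Twist2 -0.76. In MetTrp53 against Trp53 tumours the endothelial list had -0.034 with scaling, -0.21 with date, -0.15 with period and -0.088 within period 2, and Eef1a1 0.52, 0.13 and 0.22 in the last 3. Proliferation in Trp53 against Met tumours had -0.000989 with scaling. In spindloid tumours within period 2, endothelial was -0.13, fibroblast -0.13, interferon 0.15 and Wnt targets -0.078 (-0.059 within date 6). Within date 6 the genes were Cdh1 1.78, Cldn1 1.45, Mmp3 -0.089, Prrx1 -0.11, Rgs17 -0.41, Twist2 -0.16. In the interaction interferon was 0.71 with date as a block, and with 1 tumour per animal epithelial was 0.18 and proliferation -0.17, and milk in parity -0.048 within period 1. The cause was not tested, beyond the fact that date 3 held the spindloid Met tumour and 2 MetTrp53 tumours that were not spindloid.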

Other observations

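The 4 tumours labelled Intermediate were in neither group of the spindloid comparison. Their mean log2 ratios (SD) were -0.14 ± 0.43 for the claudin list, -0.80 ± 0.67 for epithelial adhesion, 0.54 ± 0.42 for EMT transcription factors, 0.87 ± 0.24 for mesenchymal genes and 2.49 ± 1.25 for Met neighbours. In the same order, the 13 spindloid tumours had 0.43 ± 0.58, -0.31 ± 0.77, 0.15 ± 0.20, 0.65 ± 0.44 and 2.45 ± 0.79, and the 13 tumours of other pathology 3.24 ± 1.22, 2.64 ± 1.31, -1.88 ± 1.21, -1.12 ± 1.22 and 0.80 ± 1.16.

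Among the 7 Met tumours of other pathology, the mean of the Met neighbours was 2.54 in Met tumour 4 and -0.53 to 0.52 in the other 6.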
